A study of Arabidopsis thaliana with 63 samples.

How the data were processed

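Leaf RNA of Arabidopsis thaliana accession Col-0 was measured by mRNA sequencing in 63 libraries, 3 from each of 21 groups. The groups were 3 genotypes, WT and the lines VPZ#2 and VPZ#4, in each of 7 conditions. The conditions were control light at 0, 6 and 30 h, fluctuating light at 6 and 30 h, and high light at 6 and 30 h. Per the labels, plants were 21 days old at the start of the treatment and the triplicates were biologically independent. For the third VPZ#2 library of control 0 h, the line given in the labels differed from its title and description, and the title and description were used.

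Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with TopHat2 2.1.1, counted per gene with featureCounts and normalised with DESeq2. The genome build and annotation were not given, and the libraries were not stranded. The deposited values are a signal that is never negative, gene counts divided by the size factor of each library (DESeq2-normalised counts), for 33295 genes. Dividing by the smallest step of each library gave whole numbers for 100% of the values at a tolerance of 1e-06, so the reads per gene could be recovered. Depth was 3.53 to 8.77 M reads per library, with a median of 5.83 M and 364.2 M in all, and the size factors ran from 0.687 to 1.735. At this depth, the counting error of a gene with few reads is large, and genes near 0 give fold changes that depend on the pseudocount. The reference table of assembly TAIR10.1 held 33010 of the gene identifiers and gave their symbols. The other 285 were chloroplast and mitochondrial genes. No coordinates were taken from it.

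Values were used as log2(value + 1), so a log2 change understates the change of genes with low values. It compares means of log2 values, so it can differ from the ratio of the group means printed beside it, which a single high library can carry. The 17189 genes with a mean of at least 10 over all libraries were tested with limma 3.58.1 in R 4.3.3, with a linear model of the 21 groups over the 63 libraries and an intensity trend in the moderated variance. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05 with no minimum fold. Every adjusted p of a gene comes from this fit unless another tool is named. Responses to fluctuating and high light were taken against control light of the same hour and, following the labels, against the sample before treatment. For the VPZ lines the response was the mean of both. Differences in response between VPZ and WT were tested as interaction terms. The lines were compared with WT at 0 h and over the mean of the 7 conditions.

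A set of 22 gene lists, with 367 loci of which 332 were tested, was written before the data were examined: light-harvesting antenna, photosystem subunits, light-stress antenna relatives, electron transport regulation and photoprotection, flavonoid synthesis, carotenoid synthesis, chlorophyll synthesis, Calvin cycle, photorespiration, antioxidants, reactive oxygen markers, heat shock, circadian clock, cold-regulated genes, abscisic acid, salicylic acid, jasmonate, starch, carbon starvation, shade avoidance, markers of other leaf cell types and organs, and the introduced genes. Of the loci, 21 had no matching symbol. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 528 list tests, 213 were called with the preset correlation and 3 with the estimated one.

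The genes followed through the alternatives were picked by a rule also fixed before the data were examined. It took VDE, PSBS and ZEP for any comparison of lines. From each list called, or with at least 3 called members, it took up to 3 called members of largest change. It then took the 4 largest rises and 4 largest falls among genes with a symbol, a mean of at least 100 in the higher group and no overlap between replicates, or the same sign in both lines or in all 7 conditions. At most 30 genes were kept per comparison, the introduced genes and the largest changes first. A gene named outside the rule is said to be so. Members of lists that were not called are named as values alone.

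The calculations were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Each gene was drawn on its own, with no variation shared by the genes of a library, unlike the real libraries. The false shares below may therefore not hold for the real data. In the setting of WT high light 6 h against control (17098 genes), limma called 20 of the 2-fold and 80 of the 4-fold genes, with 6.5% of its calls false. For the fluctuating light 6 h response of VPZ (17106 genes) it called 58 and 88, with 5.2% false. For VPZ#2 against WT over all conditions (17113 genes) it called 89 and 96, with 7% false, and for the difference in response at 30 h of high light (17091 genes) 12 and 58, with 6.7% false. In the WT high light setting DESeq2 called 30 and 87, with 17% of its calls false. The alternatives, set before the data were examined, were pseudocounts of 0.5 and 8, no filter, scaling to the library total or the upper quartile, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fit of the compared libraries alone, a replicate block, a minimum of 2-fold and leaving out each library. Correlations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9. Transcript lengths came from the reference annotation for 17142 (99.7%) of the tested genes.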

Results

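The data describe how rosette leaves of Arabidopsis thaliana responded to fluctuating light and to high light, in WT and in 2 lines, VPZ#2 and VPZ#4. The VPZ lines carry added copies of VDE, PSBS and ZEP. VDE and ZEP are the enzymes that turn violaxanthin into zeaxanthin and back, and PSBS is the photosystem subunit that switches on the dissipation of excess light as heat. Plants were grown at 125 µmol photons m-2 s-1 with 12 h of light and 12 h of dark. Fluctuating light gave 5 min of low light (50 in the same unit) and 1 min of strong light (500) in turn, a mean of 125, and high light was 500 throughout. Leaves were sampled at 0, 6 and 30 h, with 3 libraries in each of the 21 groups, and the 0 h sample preceded the treatment. The values are normalised read counts, at a depth of 3.53 to 8.77 M reads per library.

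In WT before treatment the introduced genes stood at means of 212 for VDE (AT1G08550), 6730 for PSBS (AT1G44575) and 1680 for ZEP (AT5G67030), with SDs of 186, 7090 and 631 (n = 3). In VPZ#2 the means were 602, 15800 and 4010, and in VPZ#4 they were 961, 23900 and 6160. Reads from the added and the native copies cannot be told apart. A small heat shock gene that is not among the 3 introduced genes, HSP18.2 (AT5G59720), ran from 1.96 to 81.8 in the 21 WT libraries and stood above every WT library in 30 of 42 VPZ libraries. In the 3 libraries labelled VPZ#4 fluctuating light 30 h it lay between 4.74 and 5.36. There VDE averaged 842, PSBS 3910 and ZEP 1300, against 1130, 5730 and 1430 in WT of that condition, so these libraries lacked the excess of the introduced genes seen in VPZ#2, whose means were 1500, 21200 and 4260. HSP18.2 was also within the WT range in 9 other VPZ libraries: replicates 1 and 3 of VPZ#4 control 6 h, 2 and 3 of VPZ#4 control 30 h, 3 of VPZ#4 high light 6 h, 1 and 3 of VPZ#4 high light 30 h, and replicate 2 of VPZ#2 control 30 h and of VPZ#2 high light 30 h. Among these ZEP stood at 786 and 591 in VPZ#4 control 6 h, at 731 in replicate 3 of VPZ#4 control 30 h and at 831 in VPZ#2 control 30 h, near the WT level, while PSBS in those of VPZ#4 control 6 h, at 10800 and 8670, lay above the highest WT library of the condition, at 6890. In the rest of these libraries ZEP ran from 1240 to 2530, in each above the highest WT library of its condition. Several VPZ group means thus mix libraries with HSP18.2 above and within the WT range. HSP18.2 and the count of libraries above WT were chosen after the values were seen.

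The log2 values of replicates of a group correlated across genes with a median r of 0.932, from 0.472 to 0.978, and genes are not independent replicates. The lowest agreement was in WT at 0 h, where the defence gene PR1 (AT2G14610) ran from 0 to 55900. In 5 libraries the deviation from the other replicates was large while the other two were alike: replicate 3 of WT control 0 h and of WT fluctuating light 30 h, and replicate 2 of VPZ#4 control 0 h, fluctuating light 6 h and high light 30 h. The chloroplast-encoded genes took 0.022 to 0.125% of the reads and the 10 largest genes 5.9 to 21.1%. The labels give no batch or date. Scaling to the library total moved the median of all genes by −0.48 to 0.27 log2 in single libraries, and the upper quartile by −0.3 to 0.13. Of the 213 called lists none had a median of the other sign under either scaling, which shifts all genes of a comparison together and does not bear on the list test, and the median that came nearest to 0 under a scaling was that of carotenoid synthesis in WT at 6 h of high light, from 0.35 to 0.01 with the library total. With 1 library left out, a check added after the values were seen, 107 of the 213 calls were lost at least once and 14 medians changed sign. No called list had a mean or a median opposite to its test. Among the lists not called some did, as heat shock in VPZ#2 at 0 h, with a median of −0.16 and a mean of 0.65. When the correlation was estimated, 3 list calls held: the clock list in WT at 30 h of fluctuating light, and the introduced genes at 0 h in VPZ#2 and in VPZ#4. All other list calls rest on the preset correlation.

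High light in WT raised genes of pigment synthesis, photoprotection and carbon fixation. After 6 h against control light of the same hour, ELIP2 (AT4G14690) rose by 7.95 log2, from 1.14 to 494, and ELIP1 (AT3G22840) by 5.32, from 46.4 to 1190 ± 150 (SD, n = 3). Both encode relatives of the antenna proteins that bind free chlorophyll in excess light. BAM5, a beta-amylase, rose by 7.17, the late embryogenesis gene LEA3 by 5.54, and the cold-regulated COR15A (AT2G42540) by 5.26, from 295 to 8610. Flavonol synthase FLS1 rose by 5.43 and chalcone synthase CHS by 5.28. The plastid superoxide dismutase gene CSD2 rose by 3.50, from 82.6 to 1000, the Rubisco small subunit RBCS1A by 2.31, from 68700 to 326000, and the photorespiratory reductase HPR1 by 2.1. The largest falls were in PR1, ARD3, GLP9 and GRXS13, by −7.32, −7.01, −6.55 and −6.49, and the starvation marker DIN10 fell by 5.21, from 347 to 8.16. The call of PR1 (adjusted p 0.04) was lost in 5 of the 6 fits that left out 1 library.

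The test called 5606 of 17189 genes at 6 h of high light, 2857 up and 2749 down. ELIP2 had an SE of 1.06 and an adjusted p of 3.9e-07, and COR15A an SE of 0.87 and an adjusted p of 1.4e-05. In the Calvin cycle 13 of 19 rose (16 adjusted over the list alone, median 1.47, camera adjusted p 2e-05, and adjusted p = 0.62 with an estimated correlation). In photorespiration 13 of 16 rose (median 1.29, 3.7e-05), in flavonoid synthesis 9 of 19 (10 adjusted over the list alone, median 2.49, 0.00023), and among antioxidants 14 of 23, with 1 fall (median 1.23, 0.00023). Of 11 cold-regulated genes 7 rose (9 adjusted over the list alone, median 2.42, 2e-05), and of 8 light-stress antenna relatives 7 did (8 adjusted over the list alone, median 1.58, 1.7e-04). Electron transport regulation (11 of 21 up and 1 down, adjusted p 0.0022), starch (8 of 16 up, 0.0061) and carotenoid synthesis (6 of 17 up and 1 down, median 0.35, 0.01 when scaled to the library total, 0.033) were also called upward. The calls of these 3 lists were lost without replicate 2 of WT control 6 h, and that of carotenoid synthesis also without replicate 3 of high light 6 h. Salicylic acid genes fell, 9 of 16 (12 adjusted over the list alone, median −2.97, 0.00086), and so did 5 of 8 starvation markers (median −1.91, 0.003). The lowest adjusted p of these with an estimated correlation was 0.29.

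The lists left uncalled at 6 h of high light in WT were the antenna (3 of 21 up, adjusted p 0.18), photosystem subunits (2 of 27 up, 0.073), chlorophyll synthesis (4 of 18 up, 0.073), heat shock (0 up and 4 down of 11, 0.073), the clock (5 of 19 up, 0.39), reactive oxygen markers (2 up and 1 down of 14), abscisic acid (1 up of 13), jasmonate (3 up of 15), shade avoidance (2 up of 9) and markers of other leaf cell types (1 up of 8, 0.89). Of the introduced genes' native copies 1 of 3 rose (2 adjusted over the list alone). The count was 1732 with only the libraries compared, and fell to 3399 without replicate 1 of WT high light 6 h and to 3679 without replicate 2 of WT control 6 h. Scaling to the library total, which shifted all genes by −0.34, took the share of rises from 51.0% to 29.8%.

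Anthocyanin synthesis led the WT response after 30 h of high light. DFR (AT5G42800), listed at 0 in all 3 control libraries, averaged 2430 ± 604 (SD, n = 3), a log2 change of 11.22 that depends on the pseudocount. LDOX, the next enzyme of the pathway, rose by 10.52, from 1.49 to 2590, and GSTF12, which carries anthocyanins to the vacuole, by 10.25, from 0.679 to 2040. ELIP2 rose by 9.81 and ELIP1 by 9.43, from 16.8 to 13100 ± 6110. The tocopherol cyclase VTE1 rose by 3.16, GPX7 by 4.42, the starch synthase GBSS1 by 4.02 and the minor antenna gene LHCB4.3 by 2.95, from 995 to 7610. The germin gene GER3 (−8.86), the sulfotransferase gene ST2A (−7.52), BZIP61 (−6.61) and the auxin response gene IAA29 (−6.22) fell. The protochlorophyllide reductases fell too. PORA (AT5G54190) fell by 6.24, and PORB (AT4G27440), at −3.97, went from 13700 to 1010. PGLP1 fell by 8.49, but this locus lay near 0 in 12 of the 63 libraries and shares 95.2% of its 31-base words with another gene, so its counts are uncertain.

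Of 6103 genes called, 2903 rose and 3200 fell. ELIP1 had an SE of 0.97 and an adjusted p of 1e-09, GSTF12 an SE of 1.53 and 1.4e-06, and GER3 an SE of 2.11 and 0.00094. Flavonoid genes rose in 18 of 19 (19 adjusted over the list alone, median 6.45, camera adjusted p 5.1e-14, and adjusted p = 0.21 with an estimated correlation). Electron transport regulation (13 of 21 up, median 1.2), antioxidants (14 of 23 up and 1 down, median 1.02) and photorespiration (11 of 16 up and 1 down, median 1.44) had adjusted p 1.9e-05. Light-stress antenna relatives rose in 6 of 8 (3.1e-05) and Calvin cycle genes in 7 of 19 (8 adjusted over the list alone, 0.003), and starvation markers fell in 7 of 8 (median −2.99, 0.00088). With an estimated correlation the lowest adjusted p of these was 0.1. The clock list (5 up and 10 down of 19, 0.27), shade avoidance (2 up and 5 down of 9, 0.17), chlorophyll synthesis (0 up and 3 down of 18, 0.16) and salicylic acid (0 up and 2 down of 16, 0.18) were not called. Changes followed transcript length (Spearman's rho −0.28 across genes). Under library-total scaling, a shift of −0.27, the share of rises went from 47.6% to 29.1%.

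**Figure D1:**
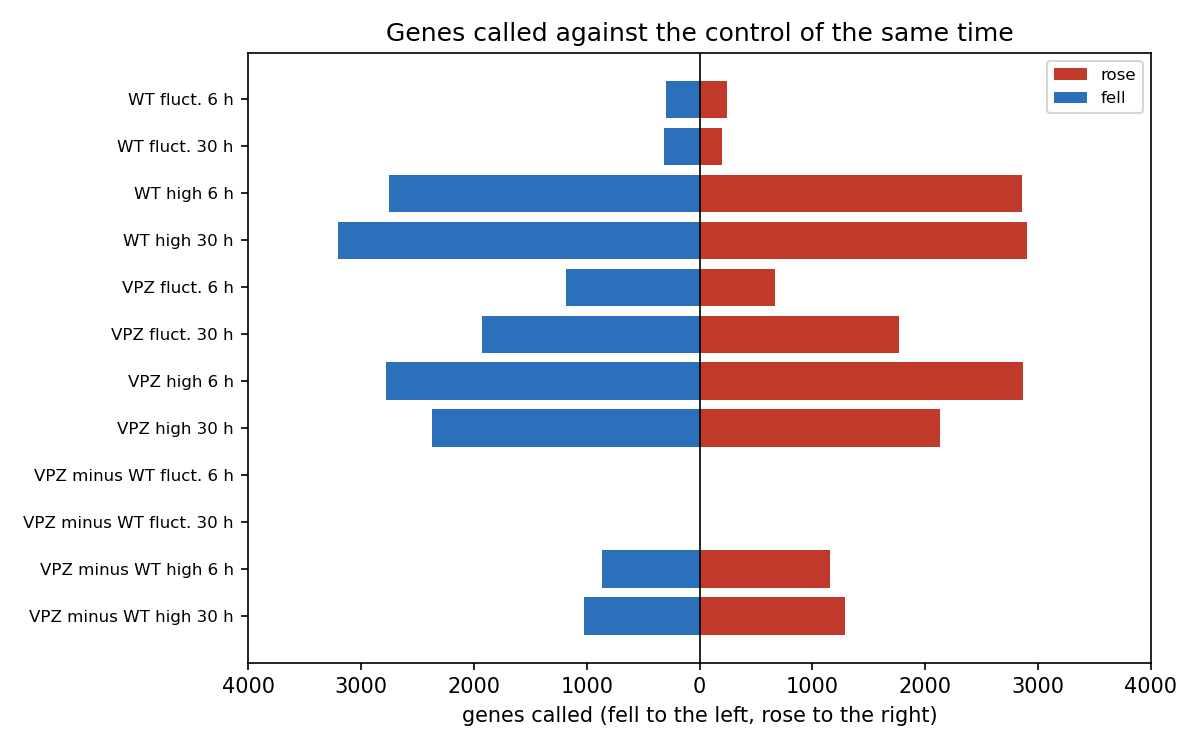
Genes called up and down (counts, bars from 0) at an adjusted p below 0.05, for the light responses of WT and VPZ and their differences. The responses to high light in WT, 5606 genes at 6 h and 6103 at 30 h, exceed those to fluctuating light, 540 and 512.

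Fluctuating light of the same mean intensity changed fewer genes in WT. After 6 h the clock genes LNK1 (AT5G64170) and ZTL (AT5G57360) rose by 1.06 and 0.90, LNK1 from 243 to 461. The plastid sigma factor SIGE rose by 1.97, from 101 to 400, the transcription factor MYB77 by 1.87, and AAO3, the last enzyme of abscisic acid synthesis, by 1.34. The glucosinolate-linked gene ESM1 fell by 4.64, from 2670 to 76.8, as did PLAT2 (−3.97), AGP17 (−3.13) and EXL3 (−3.04). Of the 19 clock genes 2 rose (3 adjusted over the list alone, median 0.32, camera adjusted p 0.044), and 1 of 13 abscisic acid genes did (median 0.81, 0.019). Photosystem subunits had a median of −0.87 with 0 of 27 called (camera adjusted p 1.6e-05), the antenna −0.98 with 0 of 21 (0.0026), the Calvin cycle −0.64 with 0 of 19 (0.014), flavonoid synthesis −1.93 with 0 of 19 (0.014) and starch −0.65 with 0 of 16 (3 falls adjusted over the list alone, 0.014). All of these had adjusted p = 0.85 with an estimated correlation. Values of the 16 salicylic acid genes were all higher, with a median of 1.27, and not called (adjusted p 0.06).

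The 540 calls of fluctuating light at 6 h (240 up, 300 down) rested on single libraries. ESM1 had an SE of 1.21 and an adjusted p of 0.028, and MYB77 an SE of 0.36 and 0.0091. Without WT control 6 h replicate 3 there were 4 calls, without replicate 2 there were 2728 and without replicate 1 there were 274. Without replicates 1, 2 or 3 of fluctuating light there were 58, 134 and 115. Each of the 11 genes picked by the rule lost its call in at least 1 of these fits, and so did 6 of the 7 lists called, all but the photosystem list. Fitting only the 6 libraries compared gave 0 calls. The share of rises, 44.4%, was 32.6% with scaling to the library total and 25.4% to the upper quartile (a shift of −0.13), and the length trend had a rho of 0.15.

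Among clock genes, 4 rose after 30 h of fluctuating light in WT. ELF4 (AT2G40080) rose by 1.96, from 51.2 ± 4.24 to 222 ± 122 (SD, n = 3), FKF1 by 1.84 and TOC1 by 1.45, from 181 to 499. The thylakoid kinase STN7 (AT1G68830), which balances light between the photosystems, rose by 0.64, from 438 to 690, and the photorespiratory aminotransferase GGT1 by 0.89. EXLA1 rose by 3.67, from 28 to 394, ATL15 by 3.54, PP2-A13 by 3.27 and GAMMA-VPE by 2.63. BAM5 fell by 4.13, as did the nucleolar fibrillarin gene FIB2 (−2.36), HDT4 (−1.98) and RACK1B_AT (−1.92). Of 512 calls 198 rose and 314 fell. The clock list was called upward with 4 of 19 members (8 adjusted over the list alone, median 0.57, 2.2e-05) and held with an estimated correlation (0.021). Electron transport regulation (1 of 21 up, median 0.26, 0.029), photorespiration (1 of 16 up, median 0.57, 0.019) and starvation markers (0 of 8, median 0.88, 0.019) were called upward. Chlorophyll synthesis (0 of 18, 1 fall adjusted over the list alone, median −0.44) and jasmonate (0 of 15, median −0.81) were called downward at 0.019. These other calls had adjusted p = 0.99 with an estimated correlation. Without replicate 1 or 3 of fluctuating light 30 h there were 339 and 144 calls, and without control 30 h replicate 1 or 2 there were 192 and 203. ELF4, EXLA1 and PP2-A13 kept their calls in all 6 such fits, and so did the clock list, while the 5 other list calls were each lost at least once. With only the libraries compared there were 0 calls. Rises were 38.7% of calls, and 24.3% under library-total and 28.2% under upper-quartile scaling.

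In the overlap of the WT responses at 6 h, 24 genes rose and 14 fell in both lights, and 216 were called in opposite directions. Independent lists would share 39.9 and 48, and simulated unchanged groups against the same controls shared 0 and 0.01 on average. Few genes can be called in unchanged groups, so these simulated counts are no baseline for the overlap. The correlation of log2 changes was −0.47 across genes, against 0.46 in the simulation, and the covariance was −0.431 against 0.131. At 30 h 97 genes rose and 71 fell in both, with 32 opposite, against products of 33.4 and 58.5. The correlation was 0.24 against 0.47 and the covariance 0.191 against 0.141. The 3 control libraries cannot be split into parts of at least 2, so part of the excess over the products at 30 h may come from the shared controls. At 6 h the counts in the same direction lay below the products.

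Set directly against fluctuating light in WT, high light at 6 h raised BAM5 by 9.05, from 2.6 to 3020, and CHS by 8.39, from 11.8 to 4040. The germin GER3 rose by 8.01, MLP423 by 8.10, ELIP2 by 7.70 and the dehydroascorbate reductase DHAR1 by 4.21, from 393 to 8430. PR1 fell by 8.25, from 57200 to 486, as did AATP1 (−8.05), ARD3 (−8.01) and GRXS13 (−7.69). DIN10 fell by 5.44. All 19 Calvin cycle genes rose (median 1.93, camera adjusted p 1.8e-05, and adjusted p = 0.59 with an estimated correlation), as did 15 of 19 flavonoid genes (median 4.94, 0.00021), 17 of 27 photosystem genes (median 1.47) and 12 of 21 antenna genes (13 adjusted over the list alone), while 14 of 16 salicylic acid genes fell (median −4.11, 0.00063). The test called 9805 genes, 4762 up and 5043 down, with an SE of 1.2 and an adjusted p of 2.7e-07 for CHS. The share of rises was 48.6%, and 33.3% when scaled to the library total, a shift of −0.43. At upper-quartile scaling the shift was 0.15.

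The same contrast at 30 h was led by anthocyanin genes again. DFR rose by 10.95, from 0.239 to 2430, ELIP1 by 10.77, from 7.19 to 13100, and LDOX by 10.28. UGT79B1, listed at 0 in fluctuating light, averaged 902. The cytosolic ascorbate peroxidase APX1 rose by 3.32, from 495 to 4960, and GBSS1 by 3.94. DIN10 fell by 6.75, from 661 to 5.75, as did GER3 (−7.56) and FKF1 (−4.89). ST2A, at 125 in fluctuating light, was listed at 0 in high light, and PGLP1 fell by 8.37, with the uncertainty given above. All 19 flavonoid genes rose (median 7.18, 1.7e-14, and adjusted p = 0.12 with an estimated correlation), 7 of 8 starvation markers fell (median −3.83), and clock genes leaned down, 12 of 19 with 3 up (median −1.29, 0.0025). Of 6208 genes 3006 rose and 3202 fell, with an SE of 0.97 and an adjusted p of 2.2e-11 for ELIP1. The length trend had a rho of −0.32, and the share of rises, 48.4%, was 33.1% when scaled to the library total (shift −0.25).

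Against the sample before treatment, WT in control light differed later (cause not tested). Changes from 0 h under treatment need not come from it. At 6 h in control light the clock gene LHY (AT1G01060) fell by 6.18, from 3950 ± 1050 to 54.8 ± 21.5 (SD, n = 3). MYBL2, a repressor of anthocyanin synthesis, rose by 6.61, from 5.4 to 633, CCL by 6.01 and OFP16 by 6.10, while NUDT8, listed at 0 before treatment, averaged 199. PORB rose by 5.01, from 300 to 5330, and the catalase gene CAT3 by 3.45, from 1650 to 19200. ELIP2 fell by 5.57, as did the beta-amylase BMY3 (−5.27), the ammonium transporter AMT1;2 (−5.08) and GBSS1 (−4.95). The test called 4330 genes (2048 up, 2282 down), with an SE of 0.67 and an adjusted p of 1.6e-09 for LHY, and 2627 without replicate 3 of control 6 h. Fitting only the libraries compared called 0 genes. Photosystem genes rose in 8 of 27 (16 adjusted over the list alone, median 1.19, 0.0011), antenna genes in 11 of 21 with 1 fall (14 and 1 adjusted over the list alone, median 1.61, 0.0026), and flavonoid genes fell in 8 of 19 (9 adjusted over the list alone, median −1.48, 0.01). Each had an adjusted p of 0.91 with an estimated correlation. Without replicate 2 of control 0 h the photosystem and antenna medians were 0.23 and 0.46 and neither list was called, and the flavonoid call was lost without replicate 3 of control 0 h and without replicates 2 or 3 of control 6 h. The share of rises was 47.3%, and 63.3% with upper-quartile scaling (shift 0.18), and the length trend had a rho of −0.29.

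By 30 h in control light LHY stood further below its 0 h level, at 13.5 and a change of −8.06, and BMY3 (−6.02), BBX32 (−5.88) and ASG4 (−5.81) fell too. PORB rose by 6.95, from 300 to 13700, PRR5 by 6.93, from 1.33 to 252, and IAA29 by 6.07. FKF1 and NUDT8, both listed at 0 before treatment, averaged 116 and 105. The heat shock factor gene HSFA2 (−3.91) and F3H of the flavonoid pathway (−5.21) fell. Photosystem genes rose in 21 of 27 (26 adjusted over the list alone, median 1.56, 3.2e-06), antenna genes in 17 of 21 with 1 fall (median 2.08, 0.00015) and cold-regulated genes in 9 of 11 (median 3.17, 2e-05). Heat shock genes fell in 7 of 11 (median −2.94, 0.00016). No list was called with an estimated correlation (lowest adjusted p 0.59). The test called 5669 genes (3073 up, 2596 down), and 649 with only the libraries compared. PORB had an SE of 0.84 and an adjusted p of 1.7e-08. Without replicate 2 of control 0 h the antenna median was 0.85 and not called, and the photosystem median was 0.57. There were 3208 calls without that library, 9203 without its replicate 3 and 3565 without replicate 2 of control 30 h. Rises were 54.2% of calls and 71.9% with upper-quartile scaling (shift 0.25).

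Fluctuating light was set against 0 h as well. At 6 h MYBL2 rose by 6.67, from 5.4 to 558, MEE14 by 5.69, PRR5 by 5.55, from 1.33 to 97, CCL by 5.50 and CYP71B26 by 4.93. F3H fell by 6.70, from 1370 to 5.32, as did CHS (−6.20), 4CL3 (−5.82) and GBSS1 (−5.78). Flavonoid genes fell in 9 of 19 (11 adjusted over the list alone, median −2.86, 1.5e-06) and starvation markers rose in 5 of 8 (7 adjusted over the list alone, median 1.82, 0.0034). Jasmonate genes rose in 4 of 15 (median 1.05, 0.029) and cold-regulated genes in 2 of 11 (3 adjusted over the list alone, median 1.3, 0.014), and light-stress antenna relatives fell in 2 of 8 (median −0.69, 0.041). Each had adjusted p = 0.87 with an estimated correlation. The test called 3108 genes (1481 up, 1627 down), with an SE of 1.0 and an adjusted p of 2.8e-06 for F3H, and a fit of only the libraries compared called 25. The jasmonate call was lost without replicate 3 of control 0 h or of fluctuating light, and that of light-stress antenna relatives without either of these or replicate 1 of fluctuating light. There were 6503 calls without replicate 2 of control 0 h and 1460 without replicate 3. Library-total scaling shifted all genes by 0.12.

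After 30 h of fluctuating light FKF1, listed at 0 before treatment, averaged 446, and PRR5 rose by 8.39, from 1.33 to 693, and MEE14 by 7.39. PORB rose by 5.91 and CBF3, a regulator of cold tolerance, by 5.54. LHY fell by 7.92, from 3950 to 21.6, as did BBX32 (−6.45), ELIP1 (−6.25), AO (−6.12) and HSFA2 (−5.53). Antenna genes rose in 14 of 21 (17 adjusted over the list alone, median 1.98, 1.8e-05), photosystem genes in 11 of 27 (18 adjusted over the list alone, median 1.27, 1e-05) and cold-regulated genes in 8 of 11 (9 adjusted over the list alone, median 2.62, 1.1e-06), while heat shock genes fell in 6 of 11 (8 adjusted over the list alone, median −3.08, 1.8e-05). Estimating the correlation gave 0.26 as the lowest adjusted p. The test called 3843 genes (2069 up, 1774 down), with an SE of 0.67 and an adjusted p of 1e-12 for LHY, and a fit of only the libraries compared called 245. Without replicate 2 of control 0 h the antenna and photosystem medians were 0.62 and 0.29 and neither list was called. There were 2472 and 7389 calls without replicates 2 and 3 of control 0 h and 2530 without replicate 2 of fluctuating light 30 h. The share of rises, 53.8%, was 67.9% with upper-quartile scaling (shift 0.18).

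At 6 h of high light BAM5 was up by 9.29 on its 0 h level, from 2.14 to 3020, and COR15A by 7.18, from 71.2 to 8610. PRR5 rose by 7.34, PORB by 5.13, DHAR1 by 4.52 and the native VDE by 2.52, from 212 to 841. NUDT8 and the vegetative storage gene VSP1, both listed at 0 before treatment, averaged 413 and 602. The ubiquitin ligase gene UPL1 (AT1G55860) fell by 5.74, from 1320 to 35.8, as did LHY (−6.44), BMY3 (−5.56) and Hsp70-15 (−5.41). All 11 cold-regulated genes rose (median 3.7, 9.5e-07, and adjusted p = 0.26 with an estimated correlation), with 20 of 27 photosystem genes (median 1.65, 0.00013) and 15 of 21 antenna genes (median 2.01, 0.0013), and 9 of 16 salicylic acid genes fell (median −2.7, 0.023). The test called 8431 genes (4269 up, 4162 down), with an SE of 0.47 and an adjusted p of 2.6e-13 for UPL1, and a fit of only the libraries compared called 1517. Without replicate 2 of control 0 h the photosystem and antenna medians were 0.68 and 0.66 and neither list was called, and the salicylic acid call was lost without that library or replicate 1. Rises went from 50.6% of calls to 37.3% under library-total scaling (shift −0.31), while the upper quartile shifted all genes by 0.20. The length trend had a rho of −0.28.

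After 30 h of high light DFR rose by 10.29 over 0 h, from 1.16 to 2430, BAM5 by 9.30, LDOX by 9.22, UGT79B1 by 8.22 and COR15A by 6.92. ELIP1 rose by 4.52, from 646 to 13100, and ELIP2 by 4.09. HSFA2 fell by 6.86, from 316 to 1.39, as did NAC061 (−6.6), the camalexin gene CYP71A13 (−6.54) and the transporter gene ABCC7 (−6.05). Photosystem genes rose in 23 of 27 (median 1.81, 3.8e-07), antenna genes in 17 of 21 (median 2.25, 1.2e-05), flavonoid genes in 13 of 19 (median 4.17, 2.2e-05) and all 11 cold-regulated genes (median 3.26, 3.8e-07). Salicylic acid genes fell in 13 of 16 (median −4.13, 0.00029) and heat shock genes in 7 of 11 (median −3.21, 0.0002). Estimating the correlation left 0.24 as the lowest adjusted p. The test called 7593 genes (3757 up, 3836 down), with an SE of 0.87 and an adjusted p of 4.4e-08 for HSFA2, and a fit of only the libraries compared called 246. Without replicate 2 of control 0 h these photosystem and antenna medians were 0.92 and 1.03 and still called. Of the calls 49.5% were rises, with 36.7% under library-total and 62.6% under upper-quartile scaling, which shifted all genes by −0.26 and 0.25.

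In the VPZ lines fluctuating light for 6 h raised genes of photosynthetic control. VDE, PSBS and ZEP changed by 0.79, 0.80 and 0.97, which did not pass the test. STN7 rose by 0.80, from 578 to 1000, the ferric reductase gene FRO6 by 2.22, from 510 to 2360, and the morning clock gene CCA1 (AT2G46830) by 1.27, from 114 to 277. The glycine decarboxylase subunit GLDP1 rose by 1.17, GPX1 by 1.17 and the ferredoxin FD1 by 0.96. NATA1 fell by 3.42, from 1110 to 104, VSP1 and VSP2 changed by −3.13 and −2.92, and the lipoxygenase gene LOX2 fell by 1.43, from 22500 to 9220. MIR5630a, which follows PGLP1 and shares all of its sequence words with other genes, fell by 3.02 and is uncertain. The test called 1854 genes (667 up, 1187 down), with an SE of 0.12 and an adjusted p of 3.8e-06 for STN7 and 0.26 and 9.6e-05 for LOX2. The call of VSP1 was lost in 7 of 12 fits that left out 1 library. Electron transport regulation rose in 6 of 21 (8 adjusted over the list alone, median 0.53, 5.8e-06) and photorespiration in 6 of 16 (10 adjusted over the list alone, median 0.79, 5.8e-06), both with adjusted p = 0.69 with an estimated correlation. Clock genes rose in 5 of 19 (6 adjusted over the list alone, median 0.37, 0.0036), carotenoid genes in 4 of 17 (5 adjusted over the list alone, 0.00072), and jasmonate genes fell in 3 of 15 (median −0.71, 0.0081). The jasmonate call was lost without replicate 1 of VPZ#2 control 6 h and without replicate 2 of VPZ#4 control 6 h. Of the calls 36.0% were rises, and 10.7% when scaled to the library total (shift −0.20).

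The VPZ mean at 30 h of fluctuating light includes the libraries labelled VPZ#4, which lacked the excess of the introduced genes, and VDE, PSBS and ZEP changed by 0.55, 0.08 and 0.84 without passing the test. STN7 rose by 0.78, GGT1 by 1.06, from 1770 to 3660, and TOC1 by 1.17. Rises were seen in AATP1, by 4.82, the zinc finger genes ZAT7, by 3.83, and ZAT12, by 2.54, AIG1, by 3.88, and the defence regulator PAD4, by 1.98, from 284 to 1050. The desaturase ADS1 fell by 4.33, from 85.7 to 3.87, as did AZI1 (−3.58) and SOFL1 (−3.44), and CHS fell by 3.09, to a mean of 46.8 from one of 1000 that rests on 5010 in replicate 2 of VPZ#4 control 30 h. IAA29, PORA and YUC8 changed by −2.93, −2.89 and −2.44. The test called 3692 genes (1764 up, 1928 down), with an SE of 0.78 and an adjusted p of 9.2e-05 for ADS1 and 1.44 and 0.015 for AATP1. Clock genes rose in 8 of 19 (9 adjusted over the list alone, median 0.58, 0.0027, and adjusted p = 0.24 with an estimated correlation) and salicylic acid genes in 3 of 16 (11 adjusted over the list alone, median 2.01, 0.0019, and 0.97). Flavonoid genes fell in 5 of 19 (median −1.22, 0.02; not called without replicate 2 of VPZ#4 control 30 h) and chlorophyll genes in 2 of 18 (median −0.52, 0.0083). There were 2450 calls without replicate 2 of VPZ#2 fluctuating light 30 h, 1953 without replicate 3 of VPZ#4 control 30 h and 2124 without replicate 3 of VPZ#4 fluctuating light 30 h. With VPZ#2 alone there were 537, and 17 of the 30 genes picked by the rule lost their call in at least 1 fit without a library.

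High light for 6 h in the VPZ lines raised ZEP, added and native copies together, by 2.03, from 1440 to 5920, and the control mean includes 786 and 591 in replicates 1 and 3 of VPZ#4. ELIP2 rose by 6.44, from 2.01 to 226, LEA3 by 4.62, ELIP1 by 4.57 and the drought gene RD29A (AT5G52310) by 4.00, from 589 to 9440. FLS1 rose by 4.12, 4CL3 by 3.45 and FKF1 by 2.29. PR1 fell by 6.62, from 11500 to 177, as did ARD3 (−7.58), XTH25 (−6.78), KTI1 (−6.02) and DIN10 (−4.95). The test called 5646 genes (2870 up, 2776 down), with an SE of 0.35 and an adjusted p of 1.7e-05 for ZEP and 0.44 and 3.2e-09 for RD29A. Cold-regulated genes rose in 10 of 11 (1 fall adjusted over the list alone, median 2.07, 5.8e-06), clock genes in 13 of 19 with 1 fall (median 0.77, 0.00021, and adjusted p = 0.084 with an estimated correlation) and flavonoid genes in 9 of 19 (11 adjusted over the list alone, median 1.86, 0.00021). All 3 introduced genes rose (median 1.2, 0.024), and the list was not called without replicate 3 of VPZ#4 control 6 h, where ZEP stood at 591. Salicylic acid genes fell in 8 of 16 (median −2.16, 0.0015). The length trend had a rho of 0.24.

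LDOX rose in VPZ at 30 h of high light by 8.01, DFR by 7.98, UGT79B1 by 7.12, ELIP2 by 7.10 and ELIP1 by 6.90. In control light LDOX, DFR and ELIP1 stood at 1120, 820 and 1040 in replicate 2 of VPZ#4, and at no more than 1.16, 0 and 11.2 in the 5 other VPZ libraries, so the control means of 187, 137 and 181 rest on that library. In high light the means were 1990, 1420 and 3400. LHY rose by 4.25, from 19.6 to 248, GPX7 by 3.83 and STN7 by 0.94. GER3 fell by 8.87, from 1390 to 3.69, as did BZIP61 (−6.64), IAA29 (−6.58), GASA6 (−6.12) and PORB (−4.02). Of the introduced genes ZEP rose by 1.57 (adjusted p 0.000604) and PSBS by 1.24 (0.0233), and VDE, at −0.03, did not pass the test. The test called 4504 genes (2133 up, 2371 down), with an SE of 0.48 and an adjusted p of 1.3e-08 for LHY. Flavonoid genes rose in 18 of 19 (median 4.29, 4.8e-16, and adjusted p = 0.26 with an estimated correlation), photorespiration in 9 of 16 (median 0.92, 0.00011) and abscisic acid genes in 6 of 13 (7 adjusted over the list alone, median 1.05, 0.00081). Chlorophyll genes fell in 6 of 18 (7 adjusted over the list alone, median −0.62, 0.0016), shade avoidance genes in 6 of 9 with 2 rises (7 and 2 adjusted over the list alone, median −2.04, 0.0062), starvation markers in 6 of 8 (median −1.79, 0.00057) and photosystem genes in 1 of 27 (median −0.47, 0.023). The photosystem call was lost without replicate 1 of VPZ#2 or replicate 2 of VPZ#4 high light 30 h. All 30 genes picked by the rule kept their calls when any 1 library was left out.

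**Figure D2:**
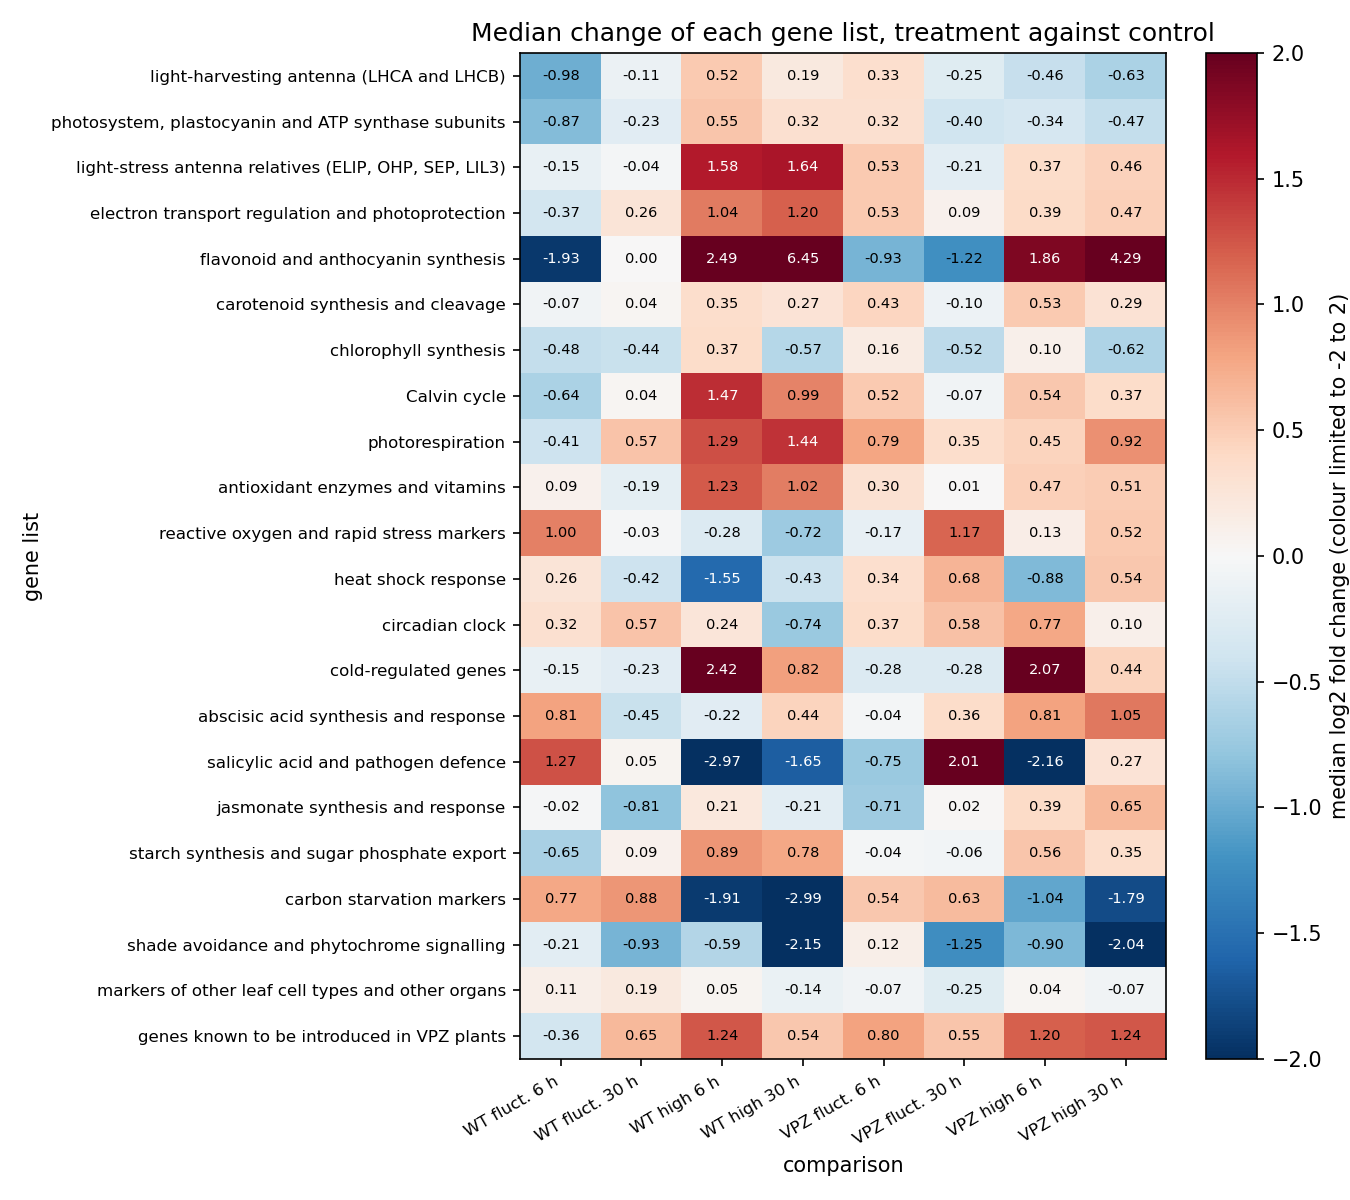
Median log2 change of each gene list (colour scale and printed value) in the responses of WT and VPZ to fluctuating and high light. Control light of the same hour is the reference, and lists called by camera are not marked. The flavonoid list stands at 6.45 in WT and 4.29 in VPZ at 30 h of high light.

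The interaction terms address whether plants with the introduced genes respond to light otherwise than WT. A response said to be more or higher in VPZ has a more positive log2 change than in WT. A response said to be less or lower has a more negative one. In fluctuating light at 6 h VDE responded by 1.16 more in VPZ than in WT (SE 0.66, adjusted p 0.41), PSBS by 1.61 (SE 0.73, 0.32) and ZEP by 0.54 (SE 0.60, 0.65), and none passed the test. No gene did with limma (0 called, 2435 at an unadjusted p under 0.05), 1 did with edgeR (2759 unadjusted) and 207 with DESeq2. Photosynthesis lists lay higher in VPZ without called members: all 27 photosystem genes were positive (median 1.17, camera adjusted p 1.2e-09), all 21 antenna genes (1.29, 3.2e-07), all 19 Calvin cycle genes (1.1, 7.9e-07) and 15 of 16 photorespiration genes (4 called adjusted over the list alone, median 0.96, 2.3e-06). All 16 salicylic acid genes were negative (median −2.61, 0.0035). The lowest adjusted p with an estimated correlation was 0.59. On leaving out any 1 library the photosystem median ran from 0.78 to 1.75, the antenna from 0.94 to 1.94, the Calvin cycle from 0.84 to 1.55, photorespiration from 0.71 to 1.25 and salicylic acid from −3.45 to −1.7, all still called. The lowest of the photosystem and antenna medians came without replicate 3 of WT control 6 h. Of the 10 lists called, those of light-stress antenna relatives, chlorophyll synthesis and starch lost their call in 6, 5 and 1 of 18 fits. Without WT control 6 h replicate 2 limma called 1210 genes, without VPZ#4 fluctuating light 6 h replicate 2 it called 50, and without WT control 6 h replicate 1 or VPZ#2 control 6 h replicate 1 it called 2 and 3. Scaling to the library total shifted all genes by −0.29.

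By 30 h of fluctuating light VDE differed in response by −0.10, PSBS by 0.33 and ZEP by 0.12, each with an adjusted p of 1, in a mean that holds the libraries labelled VPZ#4. Here too limma called 0 genes (214 at an unadjusted p under 0.05), edgeR 0 (254 unadjusted) and DESeq2 5, and limma called 0 without any 1 library. All 16 salicylic acid genes lay higher in VPZ (median 2.04, 4.9e-08), with 14 of 15 jasmonate genes (0.95, 1.9e-05), 12 of 14 reactive oxygen markers (1.23, 8.2e-05) and all 11 heat shock genes (1.12, 8.2e-05), and all 19 flavonoid genes lay lower (−0.89, 0.0041), a call lost without replicate 2 of WT or of VPZ#4 control 30 h. Of the 6 lists called, 3 had a median that moved toward 0 by over 1.5 times without some library. With an estimated correlation the lowest adjusted p was 0.52. The photorespiration list, not called, had a median of −0.13 and a mean of 0.14.

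Responses to high light differed between VPZ and WT at 6 h. ZEP rose by 1.94 more in VPZ than in WT, where it went from 573 ± 93.3 to 628 ± 187 (SD, n = 3) while VPZ#2 reached 7190 ± 175 and VPZ#4 4650 ± 2900. VDE and PSBS differed by −0.04 and −0.70 and did not pass the test. UPL1 fell in WT from 183 to 35.8 and went in VPZ#2 from 314 to 1280 and in VPZ#4 from 272 to 1200, a difference of 4.78. Over all libraries UPL1 went with the correlation of a library's deviations from the gene means with transcript length. It was at most 523 where that correlation was negative and at least 674 where it was positive. NCED5 and AAO3 of abscisic acid synthesis differed by 3.71 and 1.80, the abscisic acid response factor ABF3 by 1.39, and the clock genes PRR9 and PRR7 by 1.93 and 1.06. CSD2 responded less in VPZ by −2.91, GRP4 by −3.26, RPS13A by −2.72, DHAR1 by −2.07 and APX1 by −1.45, and RBCS1A and RBCS1B by −1.96 and −2.30.

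The test called 2017 genes at 6 h, 1154 with a higher and 863 with a lower response in VPZ. ZEP had an SE of 0.60 and an adjusted p of 0.027, and UPL1 an SE of 0.57 and 2.5e-07. The call of ZEP was lost in 4 of the 18 fits without a library (replicate 1 of WT control 6 h, of WT high light 6 h and of VPZ#4 high light 6 h, and replicate 3 of VPZ#4 control 6 h), that of APX1 in 11 and those of RBCS1A and RBCS1B in 15. Of the 25 genes picked by the rule 19 lost their call at least once, and UPL1, PRR7 and RPS13A did not. Photosystem genes (0 higher and 1 lower of 27, median −0.82) and Calvin cycle genes (2 lower of 19, 4 adjusted over the list alone, median −0.78) were called downward at 0.0084, and antioxidants (3 lower of 23, 4 adjusted over the list alone) at 0.015. Abscisic acid genes (3 of 13 higher, median 0.78, 0.044) and clock genes (3 of 19 higher, median 0.58, 0.045) were called upward. All 9 lists called lost their call in at least 1 fit: the photosystem list without replicate 2 of WT control 6 h, the Calvin cycle without that library or replicate 3 of WT high light 6 h, antioxidants without replicate 3 of WT control 6 h, and abscisic acid and clock genes in 8 and 12 of 18 fits. Each had adjusted p = 0.91 with an estimated correlation. Differences followed transcript length with a rho of 0.39 across genes, and the medians were −0.52 in the fifth of the genes with the shortest transcripts and 0.51 in the fifth with the longest. The count was 875 without replicate 1 of WT high light 6 h and 1030 with only the libraries compared. Library-total scaling, a shift of 0.32, took the share of higher responses from 57.2% to 83.5%.

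At 30 h of high light the differences in response were 1.03 for ZEP, 0.62 for VDE and −0.40 for PSBS, none of which passed the test. UPL1 fell in WT from 984 to 84.4, and stood at 1210 in VPZ#2 and 1190 in VPZ#4 after 1010 and 1040 in control light, a difference of 4.1. The clock genes BOA, PRR9 and PRR7 differed by 2.64, 2.39 and 0.87, and the transporter gene ABCC7 by 3.94. APX1 responded less in VPZ by −1.95, DHAR3 by −1.56, the NDH subunit gene NDHL by −1.74, GLO1 of photorespiration by −1.52 and CURT1A, which shapes thylakoid margins, by −1.54. IKU2, BCAT4 and ATM2 differed by −3.60, −2.46 and −2.28. PGLP1 (10.34) and MIR5630a (4.84) are uncertain, as above. The test called 2314 genes (1287 higher, 1027 lower), with an SE of 0.57 and an adjusted p of 2.7e-06 for UPL1.

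Of the lists at 30 h, photosystem genes (1 of 27 lower, 0 adjusted over the list alone, median −0.88), flavonoid genes (0 of 19, median −2.13) and antioxidants (2 of 23 lower) were called downward at 0.013 and electron transport regulation (4 of 21 lower) at 0.018. Photorespiration (3 of 16 lower and 1 higher, 6 and 1 adjusted over the list alone) had a median of −0.66 and a mean of −0.02 (0.042). These had an adjusted p of 0.83 with an estimated correlation. Without replicate 1 of VPZ#2 high light 30 h none of the 8 lists was called. The rho with transcript length was 0.42, with medians of −0.49 in the fifth of the genes with the shortest transcripts and 0.62 in the fifth with the longest. There were 1234 and 1267 calls without replicates 1 and 3 of WT high light 30 h. The share of higher responses, 55.6%, was 85.1% under library-total scaling (shift 0.32). Of the 20 called genes among those picked by the rule 13 lost their call in at least 1 of 18 fits without a library. Among those given above CURT1A lost it in 12, GLO1 in 11, ATM2 in 9, NDHL in 8, BCAT4 in 7, BOA in 6, ABCC7 in 5, DHAR3 in 4 and PRR9 in 1, while UPL1, APX1, PRR7 and IKU2 lost it in none.

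**Figure D3:**
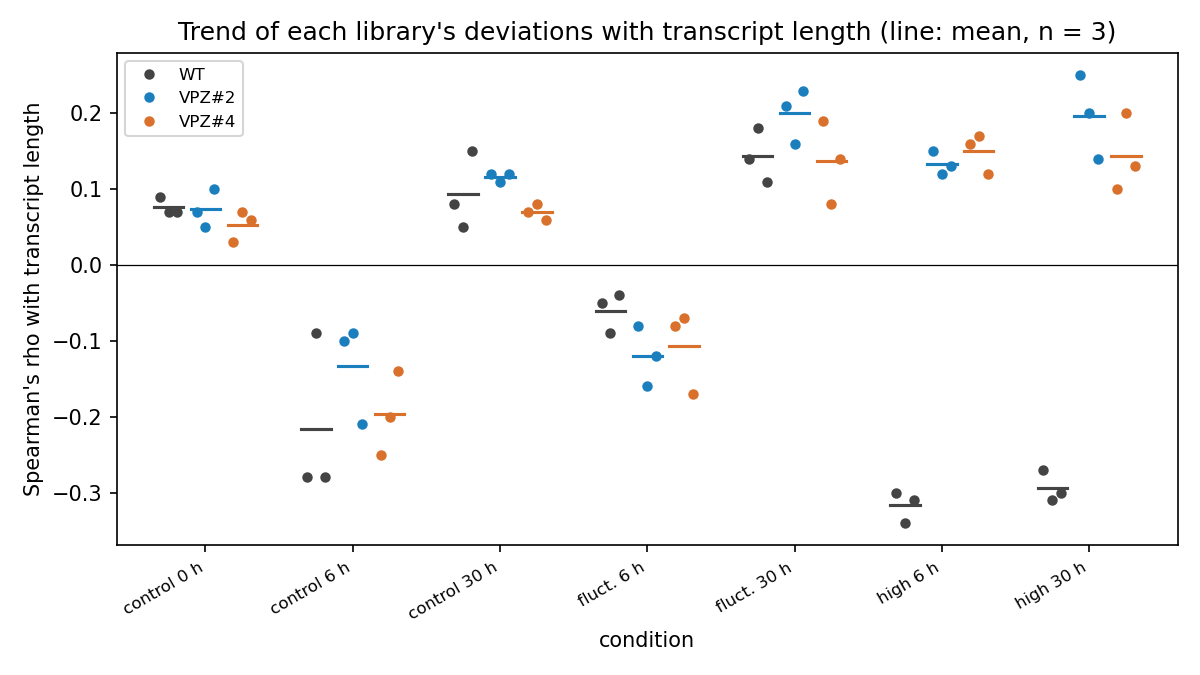
Spearman's correlation of each library's deviations with transcript length, by group. High light libraries of WT lie from −0.34 to −0.27 and those of the VPZ lines from 0.10 to 0.25.

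Before treatment VDE, PSBS and ZEP had higher means in both lines than in WT, though none was called in the test over all genes. VDE was higher by 1.92 in VPZ#2 (SE 0.54, adjusted p 1) and by 2.55 in VPZ#4 (SE 0.54, 0.096), PSBS by 1.83 and 2.42, and ZEP by 1.28 and 1.83. Adjusted over the list alone, all 3 were called in either line, and the list was called (camera adjusted p 1.7e-07 in VPZ#2 and 1.2e-07 in VPZ#4, and 0.013 and 0.022 with an estimated correlation). Without replicate 2 of WT control 0 h the median of the 3 went from 1.83 to 0.95 in VPZ#2, with 0 called over the list alone, and from 2.42 to 1.5 in VPZ#4, with all 3 still called, and camera called the list in either line. Named after their values were seen, the called genes were AT3G01345, lower by −9.19 in VPZ#2 (adjusted p 0.0424) and −9.49 in VPZ#4 (0.0234), and AT5G39790, higher by 2.25 in VPZ#2 (0.0456). Limma called 2 genes in VPZ#2 (1 up, 1 down; 307 at an unadjusted p under 0.05), edgeR 0 (286 unadjusted) and DESeq2 4. In VPZ#4 limma called 1 gene, which was lower (1391 unadjusted), edgeR 0 (1020 unadjusted) and DESeq2 5.

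At 0 h the count in VPZ#4 was 3400 without replicate 3 of WT control 0 h, 6 without replicate 2 of VPZ#4 control 0 h and 0 without replicates 1 or 2 of WT. In VPZ#2 it was 0 without replicates 1 or 2 of WT or any VPZ#2 library. All 19 Calvin cycle genes lay higher in VPZ#4 (14 adjusted over the list alone, median 1.13, 9.9e-12) and in VPZ#2 (median 0.55, 6.2e-06), as did all 27 photosystem genes (medians 0.94 and 0.53), but this rested on replicate 2 of WT control 0 h. Without it the Calvin cycle medians were 0.19 in VPZ#4 and −0.38 in VPZ#2, the photosystem medians −0.01 and −0.47 and the antenna medians −0.2 and −0.56. None of the 3 lists was then called in VPZ#4, and all 3 were called downward in VPZ#2, where they were not called either without its own replicate 2. An estimated correlation gave adjusted p of at least 0.22 for these in VPZ#4 and 0.66 in VPZ#2. The lines shared the single fall, and their log2 differences had r = 0.55 (simulated 0.46) and a covariance of 0.144 (simulated 0.124) across genes.

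Averaged over the 7 conditions, ZEP was higher by 1.76 in VPZ#2, at 3870 against 1030 in WT, and by 1.22 in VPZ#4, at 2950. PSBS was higher by 1.52 and 1.17 and VDE by 1.17 and 1.00, with the libraries labelled VPZ#4 fluctuating light 30 h included. HSP18.2 was higher by 7.40 in VPZ#2, at 2930 against 13.8, and by 4.64 in VPZ#4. The species-specific gene QQS (AT3G30720) was higher by 2.09 in VPZ#4, at 99.8 against 24.9. VSP1, VSP2 and the wax gene CER1 were higher there by 1.69, 1.66 and 1.55. In both lines the clock gene PRR9 was higher, by 0.93 and 0.83, as were the starch synthase SS4, by 0.76 and 0.94, and the chlorophyll gene CHLH, by 0.77 and 0.83. APX1 was lower by −0.87 in VPZ#2, at 1220 against 3010, and by −0.79 in VPZ#4, and AGP1 and CSD1 were lower too. The high light differences in PRR9 and APX1 enter these averages.

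The averaged test called 4008 genes in VPZ#2 (2031 up, 1977 down) and 4548 in VPZ#4 (2452 up, 2096 down). ZEP had an SE of 0.19 in both, with an adjusted p of 3.1e-09 in VPZ#2 and 5.3e-06 in VPZ#4, and HSP18.2 an SE of 0.65 with 3.4e-11 and 1.3e-06. The introduced genes as a list were called (7.8e-05 and 0.0024, with adjusted p = 0.11 and 0.24 with an estimated correlation), as were clock genes, 6 of 19 up in VPZ#2 (7 adjusted over the list alone, 0.012) and 10 of 19 in VPZ#4 (0.0021). In VPZ#4 carotenoid genes (5 of 17 up, 7 adjusted over the list alone, 0.021) and chlorophyll genes (5 of 18 up, 6 adjusted over the list alone, 0.033) were called too, but not without replicate 2 of WT control 0 h or of WT control 6 h, and chlorophyll genes in 11 of 42 fits. The lines shared 1569 rises and 1415 falls with 0 opposite, against products of 289.7 and 241.1. The simulation shared 0, which is no baseline, as above. Across genes r was 0.82 (simulated 0.49) and the covariance 0.106 (simulated 0.02). Both used the same WT libraries, so part of the excess may come from them. The length trend had a rho of 0.39 in VPZ#2 and 0.30 in VPZ#4 (−0.08 in both at 0 h), and after its removal 2579 and 3376 genes were called. The share of rises, 50.7% and 53.9%, was 74.1% and 76.4% when scaled to the library total.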

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

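The tests of explanations and the splits of the libraries in this part were chosen after the results were seen, while the tests of a difference in response were set before. 3 results are given here because a difference between groups passed a test of the difference itself. The response to 6 h of high light differed between VPZ and WT in 2017 genes, and the response to 30 h in 2314. ZEP rose by 1.94 more in VPZ than in WT at 6 h of high light (SE 0.60, adjusted p 0.027), while VDE and PSBS differed by −0.04 and −0.70. The call of ZEP was lost in 4 of 18 fits without a library, among them replicate 3 of VPZ#4 control 6 h. The VPZ libraries of this contrast were unlike, with ZEP at 786 and 591 and HSP18.2 at 7.42 and 69.4 in replicates 1 and 3 of VPZ#4 control 6 h, and at 1480 and 45.4 in replicate 3 of VPZ#4 high light 6 h, against a ZEP of 5310 and 7170 in the other two of that group.

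The log2 change of UPL1 and PRR9 with high light was more positive in VPZ than in WT at 6 and 30 h. That of APX1 was more negative. UPL1 fell in WT at both hours, while in VPZ it rose at 6 h and stayed near its control level at 30 h. UPL1 also went with the correlation of the libraries with transcript length, as given above. At 6 h the call of APX1 was lost in 11 of 18 fits without a library, and 19 of the 25 calls followed were lost at least once. Among 100 splits of the libraries into lines, the real one was the only one to reach 2017 at 6 h (highest other 1988). It was also the only one to reach 2314 at 30 h (highest other 30), which argues against chance there. At 6 h another split came close to the real count, so these splits do not exclude chance. The differences followed transcript length. Once the trend of each library was removed 1009 genes were called at 6 h, 828 of them among the 2017 (2 of 100 splits reached 1009, highest other 1361). At 30 h 1047 were called, 826 of them among the 2314 (highest other 11), which argues against the length trend as the whole cause there. At 6 h another split exceeded the real count, so the count does not settle this. At both hours part of the differences may come from the trend. WT or VPZ high light libraries made or handled apart cannot be told apart from an effect of the introduced genes, which stays open and was not tested: the WT high light libraries lie 0.37 below the lowest VPZ high light one in correlation with length, and the labels give no batch. At 6 h it was the VPZ high light libraries (0.12 to 0.17) that lay apart from their controls (−0.25 to −0.09), with WT at −0.34 to −0.30 against −0.28 to −0.09, and at 30 h the WT ones (−0.31 to −0.27 against 0.05 to 0.15), with VPZ at 0.10 to 0.25 against 0.06 to 0.12.

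In the libraries labelled VPZ#4 fluctuating light 30 h, PSBS, ZEP and HSP18.2 stood at the WT level. HSP18.2 was within the range of all WT libraries in 9 other VPZ libraries, 7 of VPZ#4 and 2 of VPZ#2. Some of these still lay above WT of their condition, as replicate 3 of VPZ#4 control 6 h, at 69.4 against 4.13 to 6.58. For WT plants in place of VPZ#4 in that group QQS was read, which was 1.99 higher than in WT of the condition (SE 0.59, unadjusted p 0.0016, adjusted p 0.59). All 3 libraries, at 40.3 to 92.1, lay above every WT library of the condition, though WT reached 60.5 in other conditions. QQS was chosen after its values were seen. HSP18.2 (at most 81.8 in WT) does not settle a swap with libraries labelled WT, as 7 other VPZ#4 libraries lay in the WT range. Silencing or loss of the introduced genes in some plants of the lines may explain the values and was not tested, and the 9 other libraries were not weighed.

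PGLP1 was below 2 in 12 of the 63 libraries, at 1.13 or less, and at 258 or more in the others. The loci that followed it over the libraries at r of at least 0.9 were AT1G38065, MIR5630a and AT5G50520. These hold 100% of their 31-base words in common with other genes. Of the 18731 loci searched, 643 (3.4%) hold nearly all of theirs in common. A candidate explanation is that reads matching several loci were counted in some libraries only, but most of the 643 did not follow PGLP1. Too few reads are argued against. The WT high light 30 h libraries, all near 0, held at least 5.89 M reads, and no VPZ#2 control 6 h library (3.53 to 5.07 M) was near 0. No biological explanation was tested.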

How the results depend on the processing

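The settings with VPZ#2 alone, with salicylic acid genes as a covariate, with the length trend removed and without libraries standing apart, and the lists with 1 library left out, were chosen after the values were seen, and the other settings before. Counts are of genes called, and the cause was not tested unless stated. Over named genes and settings 12668 values kept their side of the threshold, where uncalled ones may change sign. 1334 kept the direction and missed it (690 on leaving out a library), 16 newly passed it and 1 reversed. That was HSP17.4 in WT high light against fluctuating light at 6 h, at 0.53 with the covariate (adjusted p 0.64).

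DESeq2 called 1326 and 940 genes for WT fluctuating light at 6 and 30 h, 4 and 5 for VPZ#2 and VPZ#4 at 0 h, and 207 and 5 for the interaction in fluctuating light at 6 and 30 h. In its one simulation, of WT high light 6 h against control, 17% of its calls were false. As stated above, this share may not hold for the real data. edgeR called 0, 0 and 1 for VPZ#2 and VPZ#4 at 0 h and the interaction in fluctuating light at 6 h. With no filter there were 347 calls for WT fluctuating light 6 h and 7 and 14 for VPZ#2 and VPZ#4 at 0 h. A pseudocount of 8 gave 0 and 0 for the lines at 0 h, and the upper quartile 0 for VPZ#2. Library-total scaling gave 337 for WT fluctuating light 6 h, 4 for VPZ#4 at 0 h and 2 for the interaction in fluctuating light 6 h.

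Fitting only the libraries compared gave 0 and 0 for WT fluctuating light at 6 and 30 h and 1732 for high light 6 h. Against 0 h it gave 25 and 245 for fluctuating light, 1517 and 246 for high light and 0 and 649 for control light, at 6 and 30 h. VPZ fluctuating light gave 1194 and 8457, the interaction in high light 6 h 1030 and VPZ#2 at 0 h 1. Fewer libraries estimate the spread there. A minimum of 2-fold, which by construction removes small changes, gave 171 and 224 for the mean of VPZ#2 and VPZ#4, 866 and 1818 for VPZ fluctuating light, 2457 and 2340 for VPZ high light at 6 and 30 h and 2875 for WT control 6 h against 0 h. An estimated correlation left 3 of 213 list calls, and 107 were lost on leaving out at least 1 library, with 198 to 240 lists called in all.

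VPZ#2 alone, with fewer libraries, gave 539 and 537 for fluctuating light, 3410 and 2636 for high light, and 1065 and 1279 for the interaction in high light. This replaced a setting that left out VPZ libraries low in HSP18.2, which was dropped because it picks libraries by a measured outcome. The covariate gave 926 and 1404 for WT fluctuating light at 6 and 30 h, 6048 for WT high light against fluctuating light 6 h, 3407 for VPZ fluctuating light 6 h, 3174 for the interaction in high light 6 h, 24 and 7 for VPZ#2 and VPZ#4 at 0 h and 6345 for the VPZ#2 mean. Removing the length trend gave 272 for WT fluctuating light 6 h, 1009 and 1047 for the interaction in high light, 1 for VPZ#2 at 0 h and 2579 for its mean. Without the 5 libraries standing apart from their replicates, a choice that narrows the spread, there were 1897 and 321 for WT fluctuating light, 1989 and 8908 for the same against 0 h, 9872 for control 30 h against 0 h, 3095 and 5840 for VPZ fluctuating light, 1595 for the interaction in fluctuating light 6 h, 333 and 7870 for VPZ#2 and VPZ#4 at 0 h and 8599 for the VPZ#4 mean. Library quality weights could not be fitted because the estimate did not converge.

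Leaving out each library in turn, where a group then has the other two, WT counts ran from 4 to 2728 and 144 to 575 in fluctuating light at 6 and 30 h and from 3399 to 5991 and 4232 to 6419 in high light. Against 0 h they ran from 1460 to 6503 and 2472 to 7389 in fluctuating light, from 6642 to 10174 and 5388 to 9483 in high light and from 2627 to 4884 and 3208 to 9203 in control light. WT high light against fluctuating light ran from 8092 to 9383 and 4452 to 6466. VPZ ran from 1319 to 2107 and 1953 to 3686 in fluctuating light and from 4390 to 5681 and 3378 to 4334 in high light. VPZ#2 ran from 0 to 2 at 0 h and 3502 to 5026 in the mean, and VPZ#4 from 0 to 3400 and 3864 to 6547. The interaction ran from 0 to 1210 and 0 to 0 in fluctuating light and from 875 to 2837 and 1234 to 3112 in high light.

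Replicate numbers did not pair the libraries: deviations correlated at −0.003 for the same number and 0.002 for another, and with a replicate block VPZ#2 at 0 h had 0 calls and 215 of 528 lists were called instead of 213. Depth, 3.53 to 8.77 M reads, limits genes with few reads.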

Other observations

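HSP18.2 stood out among the heat shock genes of the VPZ lines. It was higher than in WT by 7.40 in VPZ#2 and 4.64 in VPZ#4 over the 7 conditions, while the 10 other heat shock genes had medians of −0.07 and −0.37, with 0 called in VPZ#2 and 1 fall in VPZ#4. It lay above every WT library in 19 of 21 VPZ#2 and 11 of 21 VPZ#4 libraries. QQS lay above all WT libraries of its condition in 19 of 21 VPZ#4 and 3 of 21 VPZ#2 libraries. Whether the introduced construct holds part of HSP18.2 is not stated in the labels.

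The salicylic acid genes varied among replicates of the same group. After the mean of each group was removed, their list mean over the 63 libraries followed that of the reactive oxygen markers (r = 0.93, rho 0.93), heat shock genes (0.85) and abscisic acid genes (0.69), and more weakly starvation markers (0.50) and jasmonate genes (0.34). It ran opposite to carotenoid synthesis (−0.85, rho −0.78), electron transport regulation (−0.83), chlorophyll synthesis (−0.81), the Calvin cycle (−0.80), photosystem subunits (−0.77), photorespiration (−0.73), the antenna (−0.72), light-stress antenna relatives (−0.69), starch (−0.68), antioxidants (−0.62), the introduced genes (−0.51), flavonoid synthesis (−0.45) and shade avoidance (−0.36). Of the 21 relations, those with the clock (−0.13, p 0.54), cold-regulated genes (−0.14, p 0.35) and markers of other cell types (−0.39, p 0.068) did not pass the test, and the introduced genes did not by rank (rho −0.32, p 0.069, adjusted p 0.081). The values were permuted 100000 times within groups. For reactive oxygen markers, heat shock and carotenoid synthesis p was 1e-05, the smallest these permutations can give (adjusted p 2.6e-05), and without the 2 libraries farthest out r was 0.92, 0.82 and −0.80. The labels give no batch, and these relations were computed after the values were seen.

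The splits of the libraries given next were chosen after the results were seen. ELIP2, DFR and PR1 belong to comparisons of 3 against 3 libraries, where 10 splits are too few for a share under 0.05. For WT fluctuating light 1 of 10 splits reached the real count at 6 h (540, highest other 59) and 1 at 30 h (512, highest other 1), and for high light 1 each (5606 and 1406, 6103 and 1). Against 0 h, fluctuating light had 2 of 10 at 6 h (3108, highest other 3564) and 2 at 30 h (3843, 7976). High light had 1 and 1 (8431 and 6760, 7593 and 5674) and control light 2 and 2 (4330 and 7427, 5669 and 6587). High light against fluctuating light had 1 and 1 (9805 and 114, 6208 and 1272). At 0 h, VPZ#2 had 3 of 10 (2, highest other 7625) and VPZ#4 had 4 of 10 (1, highest other 9231), and splits that call many times the real count point to a structure of the samples, such as the unlike WT replicates at 0 h.

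STN7, ELIP1 and ZEP belong to comparisons with 100 splits. The real split alone reached its count, which argues against chance, for VPZ fluctuating light at 6 h (1 of 100, 1854 against a highest other of 1156) and 30 h (1, 3692 against 545). The same held for high light at 6 h (1, 5646 against 2922) and 30 h (1, 4504 against 2172). It held too for the mean of VPZ#2 (1, 4008 against 2585). For the mean of VPZ#4 3 of 100 splits reached the real count, a share under 0.05. Yet another split called 8073 against the real 4548, which points to a structure of the samples, so chance is not excluded there. The splits of these 6 comparisons were drawn again after a first draw that could repeat a split. That draw gave 1 of 100 for the mean of VPZ#2 (highest other 3359) and of VPZ#4 (3743), 1 for VPZ fluctuating and high light at 6 h (1156 and 1914) and 2 for each at 30 h (3692 and 4504). For the interaction in fluctuating light limma called 0 genes, a count that all 100 splits must reach, so the splits say nothing about chance there. The highest other was 5222 at 6 h, which points to a structure of the samples, and 9 at 30 h. At an unadjusted p under 0.05 limma called 2435 and 214 genes there, edgeR called 1 and 0 after adjustment and DESeq2 207 and 5.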
